A study of Mus musculus with 12 samples.

How the data were processed

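RNA from sorted DN3 thymocytes of wild-type and TCF-1-deficient mice, and from lymphoma blasts sorted out of the thymus of TCF-1-deficient mice, was amplified with a NuGEN Pico kit and hybridised to Affymetrix Mouse Gene ST arrays, per the labels' protocols. This kit amplifies very small amounts of RNA, which can add noise between arrays. The authors deposited log2 signals per transcript cluster, made with RMA in Partek per the submitters' processing notes. RMA subtracts background, quantile-normalises the arrays and summarises the probes of a cluster. The versions and settings of these steps, and the probe set definition, are not given in the sources used here. The log base is not stated either; the range of the values and the usual output of RMA point to base 2. Since RMA forces the arrays to 1 common distribution, a change in total RNA per cell cannot be seen in these values, and differences are relative to the other genes on the array. Array signals also saturate and have a floor, so fold changes of dim and of very bright genes are understated.

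The deposited table had 35556 rows and 12 arrays, each array matched to its group by its label. Rows were named through the platform annotation: 21789 had 1 gene symbol, 1621 had several and 12146 had none here. Of the rows with 1 symbol, 21698 had a gene identifier found in the RefSeq gene table of GRCm38.p6, used for names and the order of genes along chromosomes, with no coordinates. Only rows with 1 symbol were used for genes. Where a gene had several such rows (999 genes), the row with the highest mean over all arrays stood for it. This left 19938 genes, and the 4985 with a mean under the 25th percentile (log2 4.78) were left out, leaving 14953 for the tests. No value column was left without a sample.

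Each comparison was fitted on its 2 groups alone with limma (lmFit and eBayes), two-sided, and p-values were adjusted over all genes tested by the method of Benjamini and Hochberg. Every adjusted p of a single gene comes from limma. A gene was called at an adjusted p under 0.05. The replicates are labelled biological, but the labels do not say how the mice were related, so p-values measure the spread between these samples. Of 23 gene lists written down in advance 22 had at least 5 measured members and were tested with camera, at its preset correlation of 0.01 between genes and also with the correlation estimated from the data. The erythroid list had 4 measured members and was not tested. No call of a list held with an estimated correlation: the lowest adjusted p were 0.284, 0.0904 and 0.105 in the 3 comparisons. Some lists share members, such as Lef1 (T-lineage factors, Wnt targets and T-ALL oncogenes) and Il7r (maturation and T-ALL oncogenes).

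Genes named in the text followed a rule fixed before the data were examined, as were the groups, tests, lists and most alternatives. For each comparison the rule took the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap, without predicted loci. It added up to 4 members per list with the lowest p and a fixed set of T cell genes. The deleted gene was part of the rule and its level was not analysed here. Tubb3 in the overlap and some list members were named after their values were seen.

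The batches were found by looking for rows without a gene name that split the arrays by at least 1 log2 unit. The split shown by the most such rows (35, against 14 for the next) was taken. Rows without a name do not enter the comparisons of genes. Replicate numbers were checked by correlating deviations from the group means. Same-number wild-type and TCF-1-deficient DN3 arrays correlated at 0.51, 0.42 and 0.25, and these numbers were taken to pair them. The 0.51 is for number 1, whose arrays are both in the smaller batch. Wild-type replicate 1 also correlated at 0.44 and 0.45 with lymphomas 1 and 2 of that batch. That value cannot tell pairing from batch. DN3 arrays of numbers 2 and 3 are all in the larger batch, so the 0.42 and 0.25 carry the batch as well. Pairing thus rests on their excess over the crossed pairs of that batch. Wild-type replicate 2 with TCF-1-deficient replicate 3 correlated at 0.06, and wild-type replicate 3 with TCF-1-deficient replicate 2 at -0.05. Deviations within a group sum to 0, so these values are not independent. Same-numbered lymphoma and DN3 arrays did not all correlate positively (-0.22 and -0.26 for number 2). Overlaps between the comparisons that share wild-type arrays were set against 100 simulations of unchanged groups, and against 100 in which called lymphoma changes were moved to random genes, with independent noise per array, which was added after seeing the data. Correlations across lymphomas were tested over all 720 orders of the tumours.

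Alternatives covered median-centring or repeated quantile normalisation of the arrays, no filter or a filter at the 50th percentile, averaging of rows, a trended robust variance, 1 fit to all arrays, weights per group, the replicate block and leaving out each array. The batch as a term, the larger batch alone, a term for sex read from Xist and SDs within batches were added after seeing the data.

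The test was checked on simulated data with the real means, 14953 genes and 200 genes changed per size. Each gene had 1 spread pooled over the 3 groups and independent noise, without batch, pairing or sex. The shares that follow hold for such data and need not hold for the real arrays. For TCF-1-deficient against wild-type DN3 cells the test recovered 36.5%, 92.5% and 99% of changes of 0.5, 1 and 2 log2 units, and 3.8% of calls were wrong. For lymphomas against wild-type DN3 cells the values were 64.5%, 97% and 100%, with 3.51% wrong. For lymphomas against TCF-1-deficient DN3 cells they were 64%, 97.5% and 99%, with 5.1% wrong. Computation used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with matplotlib 3.10.9 for the plots.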

Results

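Gene expression was measured in sorted mouse thymocytes with or without TCF-1, and in T cell lymphomas that arose in the thymus of mice lacking it. TCF-1 is an HMG-box transcription factor that acts early in the T cell lineage and partners beta-catenin in Wnt signalling. DN3 thymocytes carry neither CD4 nor CD8 and are rearranging the T cell receptor beta gene. The 12 arrays comprised 3 of wild-type DN3 cells, 3 of TCF-1-deficient DN3 cells and 6 of lymphoma blasts, all labelled as biological replicates. The labels put the donors of DN3 cells at 8 to 12 weeks of age and the lymphoma-bearing mice at 12 to 40 weeks, so the lymphomas differed from both DN3 groups in age as well.

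Of 19938 genes with a row of their own, 14953 were bright enough to be tested. The arrays had median log2 signals between 5.3 and 5.39, and their number limits the precision. The median SD over genes was 0.126 in wild-type DN3 cells, 0.162 in TCF-1-deficient DN3 cells and 0.153 in the lymphomas. Along the first principal component, with 33.8% of the variance, the lymphomas lay between 12.53 and 21.89 and the DN3 arrays between -19.75 and -14.00. The level of the deleted gene was not analysed here, so the genotype labels were not checked against it.

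The arrays also fell into 2 batches that the labels do not name. A set of 35 rows without a gene name had median levels of 5.88 to 6.45 on replicate 1 of both DN3 groups and replicates 1 and 2 of the lymphomas, and of 8.32 to 9.03 on the other 8 arrays. The smaller batch held the same share of each group. Within batches the median SD over genes was 0.095 in wild-type DN3 cells, 0.116 in TCF-1-deficient DN3 cells and 0.135 in the lymphomas. The groups differ in their number of arrays, so neither these SDs nor those across batches settle which group varied most. Xist, the RNA that coats the inactive X chromosome, stood at 10.10 to 10.58 on all wild-type arrays, TCF-1-deficient replicates 1 and 2 and lymphomas 3, 4 and 5. It stood at 4.13 to 4.40 on TCF-1-deficient replicate 3 and lymphomas 1, 2 and 6, where the Y-linked genes Uty and Kdm5d stood at 5.98 to 7.12 and 6.09 to 7.43. Sex is not given in the labels and was not balanced between the groups.

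The first comparison asked how DN3 cells without TCF-1 differ from wild-type DN3 cells. Cd2, a T cell adhesion receptor, showed the largest rise: its log2 signal was 9.55 ± 0.09 (SD, n = 3) without TCF-1 and 5.61 ± 0.17 (SD, n = 3) with it, a 15.3-fold difference. Lef1, the close relative of the deleted factor that binds the same DNA motif, rose by 1.01 (SE 0.13, limma adjusted p = 0.0043). The coreceptor genes Cd8a and Cd8b1 rose by 1.21 and 1.40, while Cd4 stood at 5.12 and 4.99 and was not called. The receptor for interleukin 7, Il7r, fell by 1.01 and the chemokine receptor gene Ccr9 fell by 1.14. Within the smaller and the larger array batch Cd2 differed by 4.12 and 3.85, Lef1 by 0.97 and 1.03 and Il7r by -0.91 and -1.06.

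In all, 298 genes were called at an adjusted p under 0.05, of which 85 rose and 213 fell. At 2-fold or more there were 29 rises and 36 falls. After Cd2 the largest rises belonged to Atp8a2 (2.50), Akr1c12 (2.33), Ptpn14 (2.29), Stk39 (2.08) and Agfg1 (2.06). They were followed by Afdn, Ikzf3, Adam19, Rdh10, Adgre5 and Gimap4, with rises from 1.91 down to 1.58. Ikzf3 encodes Aiolos, a lymphoid zinc-finger factor of the Ikaros family, and Gimap4 a GTPase of lymphocytes. The largest falls were those of Parp8 (-2.16), the cytosolic DNA sensor gene Aim2 (-2.07), Ctla2a (-2.07), the glutamate receptor subunit gene Gria3 (-2.06) and Atp8b4 (-1.98). Cibar1, Zbtb20, Clec2d, Sestd1, Sgk3, Ppic and Angpt1 fell by 1.34 to 1.44.

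**Figure D1:**
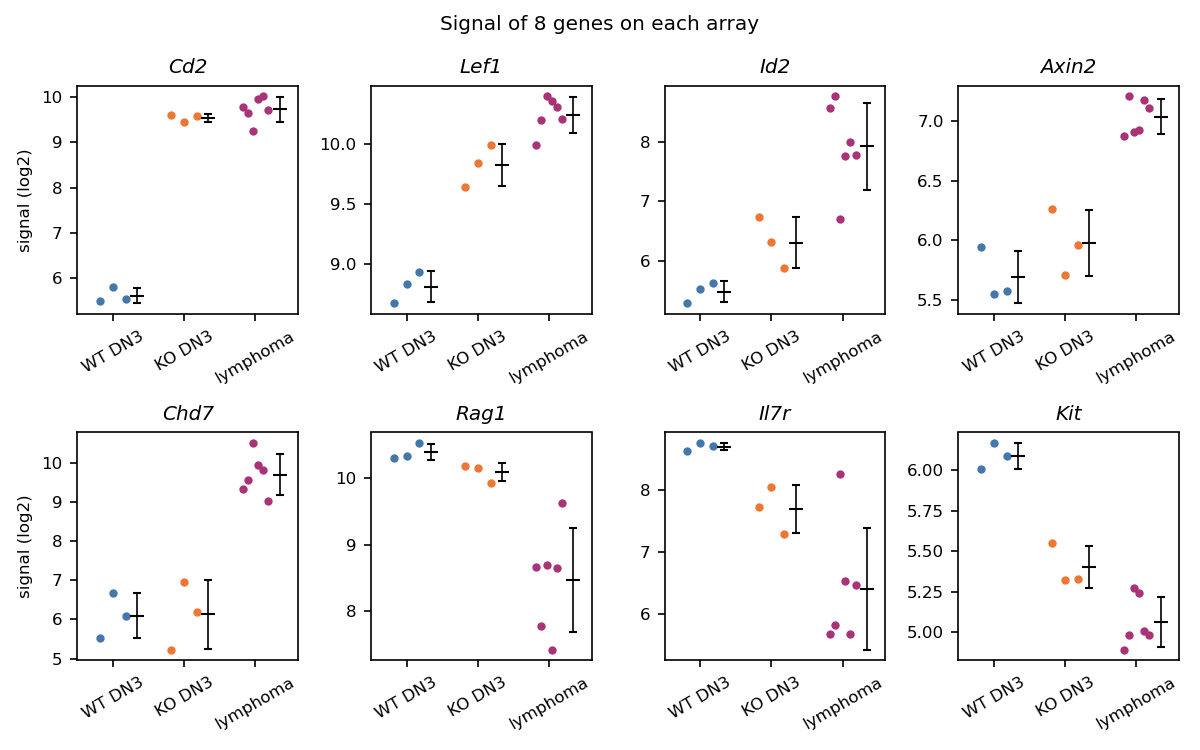
Log2 signal (vertical axes) of 8 genes on each of the 12 arrays, shown as dots beside the mean ± SD of each group, with n = 3 for wild-type and TCF-1-deficient DN3 cells and n = 6 for lymphomas. Cd2 averaged 5.61 in wild-type DN3 cells and 9.55 or more in the other groups, and Lef1 was higher on every array without TCF-1 than on the wild-type arrays.

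Among the lists of genes fixed in advance, 12 gamma-delta T cell markers were measured and 11 lay above 0, with a median change of 0.24. Of these, 1 rose over all genes (Cd163l1, a scavenger receptor, by 1.03) and 3 adjusted over the list alone, none fell and 11 did not pass. The list as a whole was called higher (camera adjusted p = 0.00272), with an adjusted p = 0.284 with an estimated correlation. The 12 markers of NK and innate lymphoid cells had a median change of 0.23 and an adjusted p of 0.0067, against an adjusted p = 0.393 with an estimated correlation. Gzma, the granzyme A gene, rose by 0.68 and was the 1 member called over all genes, with 3 higher adjusted over the list alone. Id2, an inhibitor of E proteins in that list, was 0.82 higher without being called (adjusted p = 0.0624), and was called with the replicate number as a block (adjusted p = 0.0122, with up to 0.292 over the settings).

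The 23 measured genes of G2 and mitosis were all above 0, with a median of 0.23, and none was called alone over all genes, while 3 were higher adjusted over the list alone. As a list they were called higher (adjusted p = 0.000222), with an adjusted p = 0.393 with an estimated correlation. With the replicate block, 4 members of G2 and mitosis passed over all genes, among them Bub1 (0.56), Birc5 (0.54) and Ccnb2 (0.49), and with the batch as a term 3 did. Of the 15 interferon response genes 13 lay above 0, none was called over all genes and 1 was higher adjusted over the list alone. That list was called higher at 0.0067, against an adjusted p = 0.393 with an estimated correlation. TCF-1-deficient replicate 3, the one with low Xist, stood apart from replicates 1 and 2 in part of these genes. Rtp4 was at 8.04, 7.74 and 6.72 on the 3 arrays in order, against 6.61 to 6.98 in wild-type cells. Of interferon-induced genes outside the list, Ifitm3 was at 9.24, 8.80 and 7.26, against 7.03 to 7.28, and Samd9l at 7.04, 7.39 and 5.80, against 5.96 to 6.69. The V(D)J recombination list moved down, with a median of -0.30 over 11 genes (adjusted p = 0.0301, and adjusted p = 0.36 with an estimated correlation). With 1 fit to all 12 arrays that list was not called (adjusted p = 0.135). Its 1 call over all genes was Dntt, the template-independent polymerase of junctions, which fell by 0.69, and 4 members were lower adjusted over the list alone. Nucleolar and Myc-driven biosynthesis genes had 17 of 20 members below 0 and a median of -0.23, with no member called over all genes or adjusted over the list alone. The list was called lower at 0.0067, against an adjusted p = 0.284 with an estimated correlation. The replicate block called 3 interferon response genes higher and 3 V(D)J recombination and 2 nucleolar genes lower over all genes. Among gamma-delta and NK markers it called 4 and 3 higher. That block called many more genes of any kind, as given below, so member counts with it do not by themselves set a list apart.

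Pre-TCR and CD3 signalling genes were not called as a list (adjusted p = 0.0875), although Cd2, Fyn (0.88) and Cd5 (0.63) rose, none fell, 15 of the 18 did not pass and 6 were higher and 2 lower adjusted over the list alone. Of 15 Wnt and beta-catenin targets Lef1 and Sp5 (0.67) rose, Ccnd2 (-0.72) fell and 12 did not pass, and these counts were the same adjusted over the list alone. That list had an adjusted p of 0.0875. Among 12 Notch targets Dtx1 rose by 0.63, the growth factor receptor gene Igf1r fell by 0.92 and 10 did not pass (list adjusted p = 0.798). The median change of that list was 0.05 and its mean -0.03. Further calls were Kit (-0.69) among 18 progenitor genes, Etv6 (-0.61) among 20 T-ALL tumour suppressors and Jun (-0.88) among 16 immediate-early genes. Those 3 lists had adjusted p values of 0.723, 0.103 and 0.71. The other lists not called were T-lineage transcription factors (0.25), DP and later T cell maturation (0.3), S phase (0.0875), p53 targets (0.0593), Bcl-2 family (0.295), T-ALL oncogenes (0.71) and glycolysis (0.314). Gata3, Bcl11b, Notch1, Myc, Il2ra, Ptcra, Rag1, Rag2, Hes1 and Cdkn2a were not called. With the replicate block, Rag2 (-0.50, adjusted p = 0.0139, up to 0.455 over the settings) and Hes1 (-0.60, adjusted p = 0.00909, up to 0.566) were. Over all genes the block also called 5 pre-TCR and CD3 signalling genes higher and 1 lower, 4 and 2 of DP and later T cell maturation, 1 and 3 of the T-ALL oncogenes and 2 and 2 of the Notch targets. It called 2 T-ALL tumour suppressors and 2 p53 targets lower, and 1 higher and 1 lower in each of S phase, immediate-early genes and thymic stroma. These counts too are to be read against the block's share of calls over all genes, given below. Of the lists for other cell types, B cell (0.338), myeloid and dendritic (0.129) and thymic stroma (0.0875) markers were not called. The gamma-delta and NK lists described above, also of other cell types, were called higher. None of the 4 measured erythroid genes (Klf1, Epor, Alas2 and Slc4a1) was called in any of the 3 comparisons.

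All 298 called genes had arrays that did not overlap between the groups; over all genes tested 3296 (22%) did so, where chance gives 10%. Because same-numbered DN3 arrays deviated together, the fit with the replicate number as a block is given too. It called 1380 of the 14953 genes tested, 431 higher and 949 lower, among them all 298. Small counts of list members called with the block, such as 2 of 20 nucleolar genes lower, lie near that share. The pairing behind the block was inferred from correlations. In place of the 298 without the block, 57 were called without wild-type replicate 2, and 122 and 154 without wild-type replicates 1 and 3. The count was 126 without TCF-1-deficient replicate 3, 754 with the batch as a term and 144 in the larger batch alone. The larger share of falls did not hold without wild-type replicate 2, with 31 genes higher and 26 lower, nor without TCF-1-deficient replicate 3 or with a sex term, with 68 higher and 58 lower in both. Without TCF-1-deficient replicate 2, 3 lists were called in place of 6, with adjusted p of 0.0586 for G2 and mitosis, 0.0816 for interferon response and 0.0586 for V(D)J recombination; without wild-type replicate 3 the latter lists both stood at 0.0611. Of the 41 named and called genes 25 stayed called whichever array was left out; the calls of Clec2d, Sestd1, Ppic, Angpt1, Dtx1, Fyn, Cd5, Dntt, Sp5, Ccnd2, Kit, Il7r, Gzma, Cd163l1, Etv6 and Jun did not, with adjusted p up to 0.222 (Dtx1 without wild-type replicate 2). With 1 fit to all 12 arrays 199 of the 298 calls were kept, and of these 25 genes Cd8a (0.129), Ccr9 (0.145), Gria3 (0.103), Cibar1 (0.193) and Igf1r (0.0564) were not.

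The second comparison set the lymphomas against wild-type DN3 cells. Cd2 was again the gene with the largest rise, at 9.73 ± 0.28 (SD, n = 6) against 5.61 ± 0.17 (SD, n = 3). Gimap4 rose by 3.40, Ikzf3 by 3.31 and the chromatin remodeller gene Chd7 by 3.61, or by 2.01 with the 30 rows of that gene averaged. Lef1 rose by 1.43 (SE 0.10, limma adjusted p = 5.29e-06) and Id2 by 2.44 (SE 0.35, adjusted p = 0.00099). The genes of the recombinase that assembles T cell receptors were lower: Rag1 fell by 1.92 and Rag2 by 1.39. Il7r fell by 2.30, and the survival gene Bcl2 fell by 1.13. Within the smaller and the larger batch Chd7 differed by 3.94 and 3.45, Id2 by 3.37 and 1.97 and Rag1 by -2.08 and -1.84.

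Here 871 genes were called, 443 higher and 428 lower, and 137 and 118 of them by 2-fold or more. Rises followed for Afdn (3.09), Uaca (3.05), Atp8a2 (3.01), the growth factor receptor gene Pdgfrb (2.92), Ptpn14 (2.83), Rapgef2 (2.66), the dopamine receptor gene Drd5 (2.54) and Agfg1 (2.52). The largest falls were those of the ubiquitin ligase gene Rnf130 (-3.85), Myl10 (-3.81), Dgkeos (-3.62) and Atp8b4 (-3.62). Itga4, an integrin subunit, fell by 3.58, and falls followed for the galectin gene Lgals1 (-3.18) and Parp8 (-2.95). Akr1c13, Khdc1a, the guanylate-binding protein gene Gbp8, Atxn1 and Ctla2a fell by 2.48 to 2.83, and with its rows averaged Atxn1 changed by -1.59.

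Pre-TCR and CD3 signalling genes were the list of T cell genes with the most calls: 8 of 18 rose, 3 fell and 7 did not pass, and 10 were higher and 4 lower adjusted over the list alone. After Cd2 the kinase gene Fyn rose by 1.54, Cd5 by 0.98 and the exchange factor gene Rasgrp1 by 0.91. The list was called higher (adjusted p = 0.00034), with an adjusted p = 0.0904 with an estimated correlation. Of 20 T-lineage transcription factors 7 rose, among them Ikzf3, Tox (0.79), Gata3 (0.75) and Ikzf1 (0.72), 1 fell and 12 did not pass, with 8 higher and 2 lower adjusted over the list alone. Its test was called higher at 0.0411 although its median was -0.05 and its mean 0.32, and it had an adjusted p = 0.273 with an estimated correlation and 0.0662 with the batch as a term. Among 15 Wnt and beta-catenin targets Lef1, Axin2 (1.35), the feedback inhibitor of beta-catenin, and Ccnd1 (1.14) rose, Ccnd2 (-1.72) fell and 11 did not pass, with 5 higher and 1 lower adjusted over the list alone. The list was called higher at 0.0163, against an adjusted p = 0.192 with an estimated correlation. The DP and later T cell maturation list was called higher at 0.0193, against an adjusted p = 0.277 with an estimated correlation. In it 4 of 16 genes rose, including Itm2a (2.02) and Cd8b1 (1.43), while Ly6d (-2.32) and Il7r fell and 10 did not pass, with 5 higher and 2 lower adjusted over the list alone.

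Gamma-delta T cell markers were called higher (adjusted p = 0.000495, and adjusted p = 0.286 with an estimated correlation). Etv5 (2.51), the costimulator gene Icos (1.63) and Cd163l1 (1.10) rose, none fell and 9 of 12 did not pass, with 4 higher adjusted over the list alone. NK and innate lymphoid markers were called higher at 0.0179, against an adjusted p = 0.273 with an estimated correlation. Id2, Nfil3 (1.27), Il2rb (0.93) and Gzma rose, Nkg7 (-1.50) fell and 7 of 12 did not pass, and the counts were the same adjusted over the list alone. All 23 genes of G2 and mitosis lay above 0 with a median of 0.24 and none was called over all genes or adjusted over the list alone. They were called as a list at 0.000121, against an adjusted p = 0.441 with an estimated correlation. Of 16 p53 targets Zmat3 (0.38) and Trp53inp1 (0.36) rose, none fell and 14 did not pass, with 3 higher adjusted over the list alone. The p53 list was called at 0.0297, against an adjusted p = 0.192 with an estimated correlation.

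Progenitor genes moved down: Erg (-1.34), Kit (-1.03) and Nfe2 (-0.65) fell, none rose, 15 of 18 did not pass, and 4 were lower adjusted over the list alone. The list was called lower at 0.000651, against an adjusted p = 0.159 with an estimated correlation. Nucleolar and Myc-driven biosynthesis genes had 18 of 20 members below 0, a median of -0.16 and no call over all genes or adjusted over the list alone. As a list they were called lower at 0.00248, against an adjusted p = 0.397 with an estimated correlation. Lists without a call were V(D)J recombination (0.239), where Dntt (-0.94), Rag1 and Rag2 fell and Xrcc5 (0.42) rose, Notch targets (0.79), where Dtx1 (0.92) and Heyl (0.74) rose, and Bcl-2 family (0.79). Glycolysis (0.239), immediate-early and stress genes (0.111), S phase (0.159), interferon response (0.378), T-ALL oncogenes (0.415) and T-ALL tumour suppressors (0.359) were not called either. The Notch target list had a median of -0.05 and a mean of 0.03. Markers of B cells (0.378), myeloid and dendritic cells (0.107) and thymic stroma (0.46) were not called as lists, with single falls of Cd79b (-0.95), Vpreb1 (-1.46) and Epcam (-1.05) and a rise of H2-Aa (0.47). Notch1, Myc, Hes1, Il2ra, Ptcra, Bcl11b, Cd4, Cd8a and Cdkn2a were not called.

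Of the 871 genes 846 did not overlap between the groups; 1544 (10.3%) of all genes did not, where chance gives 2.4%. The count was 564, 560 and 570 without wild-type replicates 1, 2 and 3, and 549 in the larger batch alone, and 6 lists were called in place of 10 without wild-type replicate 1, where T-lineage factors (0.0626), Wnt targets (0.0566), maturation (0.0552) and p53 targets (0.0566) lost their call. Among these 4 lists the highest adjusted p with an array left out was 0.0921 (p53 targets without wild-type replicate 3). Of the 72 named and called genes 54 stayed called whichever array was left out; those that did not were Gata3, Rag1, Rag2, Xrcc5, Heyl, Ccnd1, Cd163l1, Vpreb1, H2-Aa, Trp53inp1, Zmat3, Il7r, Nf1, Tcf12, Dnmt3a, Pfkp, Pkm and Ier2, with adjusted p up to 0.216 (Ier2 without wild-type replicate 3). In the larger batch alone the calls of Ikzf1, Il2rb, Etv5 and Bcl2 ended as well, as did those of T-lineage factors (0.0662) with the batch as a term and of p53 targets (0.0513) with the filter at the 50th percentile. Vpreb1 changed by -0.91 without wild-type replicate 1 and by -0.83, without a call, in the larger batch alone.

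**Figure D2:**
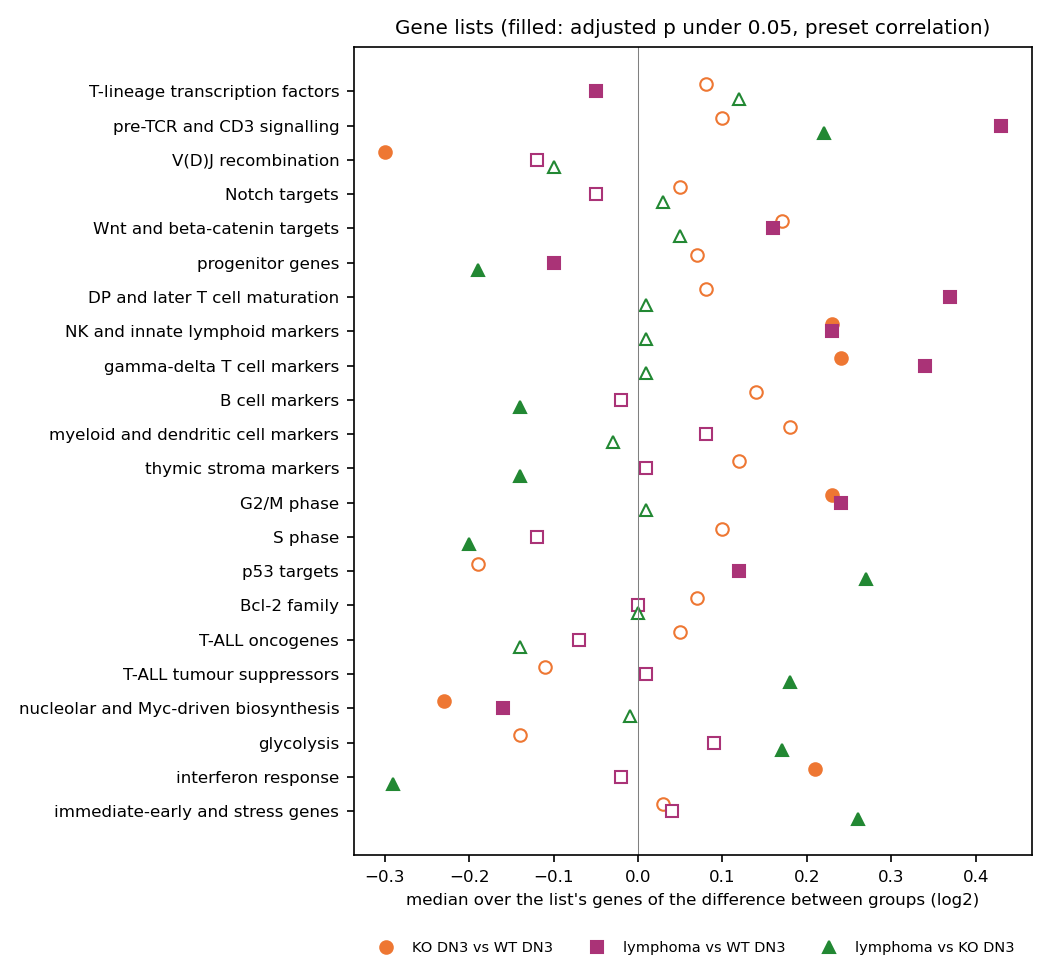
Median over each list's measured genes of the log2 difference between groups (horizontal axis), for the 22 lists tested (vertical axis) and the 3 comparisons (marker shapes), with filled markers for a camera adjusted p under 0.05 at the preset correlation; with an estimated correlation no list passed. G2 and mitosis genes had medians of 0.23 and 0.24 against wild-type DN3 cells and 0.01 in lymphomas against TCF-1-deficient DN3 cells.

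The third comparison asked what separates the tumours from the DN3 cells of the same genotype. Uaca rose by 2.68, Pdgfrb by 2.32 and Chd7 by 3.58 (SE 0.35, limma adjusted p = 0.000129), or by 1.93 with the rows of Chd7 averaged. Axin2 rose by 1.06, Id2 by 1.62 and Gata3, a transcription factor needed for T cell commitment, by 0.89. Lef1 was 10.25 ± 0.15 (SD, n = 6) against 9.82 ± 0.17 (SD, n = 3), a rise of 0.42 near the threshold (limma adjusted p = 0.0449), whose call ended without any 1 of 8 arrays (adjusted p = 0.0605 to 0.165, limma). Rag1 fell by 1.62 and Ptcra, the pre-TCR alpha chain gene, by 0.64. Within the smaller and the larger batch Chd7 differed by 4.24 and 3.25, Axin2 by 0.79 and 1.19, Lef1 by 0.45 and 0.41 and Rag1 by -1.96 and -1.44. Cd2 was not called here, at 9.73 ± 0.28 (n = 6) and 9.55 ± 0.09 (n = 3).

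The 990 called genes comprised 673 rises and 317 falls, with 89 and 57 of them at 2-fold or more. With the arrays quantile-normalised again the split was 491 to 448, or 52.3% higher in place of 68%. Ppic, Cd81, Ctnnd1, Egln3, Rapgef2, Slc44a1, Drd5, Etv5 and Itm2a rose by 1.86 to 2.48. The largest falls were those of Akr1c13 (-3.83), Myl10 (-3.32), Dgkeos (-3.19), Lgals1 (-3.17), Rnf130 (-2.95) and Itga4 (-2.85). Anxa2, the neuronal tubulin gene Tubb3, the inhibitory receptor gene Ctla4, Akr1c12, Ifitm3 and Samd9l fell by 2.50 to 2.81.

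The p53 target list was called higher (adjusted p = 0.00121, and adjusted p = 0.105 with an estimated correlation). Ei24 (1.10), Trp53inp1 (0.56), Zmat3 (0.53) and Polk (0.51) rose, none fell and 12 of 16 did not pass, with 7 higher adjusted over the list alone. T-ALL tumour suppressors were called higher at 0.0363, against an adjusted p = 0.288 with an estimated correlation. Ikzf1 (0.79), Nf1 (0.76), Dnmt3a (0.48) and Phf6 (0.47) rose, none fell and 16 of 20 did not pass, with 6 higher and 2 lower adjusted over the list alone. Pre-TCR and CD3 signalling genes were called higher at 0.0361, against an adjusted p = 0.261 with an estimated correlation. Cd28 (1.04), Fyn (0.66), Cd3e (0.59) and Rasgrp1 (0.56) rose, Ptcra fell and 13 of 18 did not pass, with 7 higher and 3 lower adjusted over the list alone. Glycolysis genes were called higher at 0.0282, against an adjusted p = 0.261 with an estimated correlation. Pkm (0.59) was the 1 of 15 members that rose, both over all genes and adjusted over the list alone. Immediate-early and stress genes were called higher at 0.0369, against an adjusted p = 0.601 with an estimated correlation. Zfp36 (1.07) and Egr1 (0.79) rose, none fell and 14 of 16 did not pass, with 4 higher adjusted over the list alone.

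All 18 progenitor genes lay below 0 with a median of -0.19; Erg (-0.96) was the 1 call, with 2 lower adjusted over the list alone. The list was called lower at 0.000923, against an adjusted p = 0.261 with an estimated correlation. Interferon response genes had 14 of 15 members below 0 and a median of -0.29, Ddx58 (-0.77) and Ifit1 (-0.44) fell, 13 did not pass, and 6 were lower adjusted over the list alone. That list was called lower at 0.00121, against an adjusted p = 0.288 with an estimated correlation. Here too TCF-1-deficient replicate 3 stood apart, nearer to the tumours: Ddx58 was at 7.07, 7.21 and 6.59 on the 3 arrays, against 6.00 to 6.37 in lymphomas, and Ifitm3 at 9.24, 8.80 and 7.26, against 5.12 to 6.08. S phase genes had 23 of 25 members below 0, with E2f2 (-0.53) the 1 call over all genes and adjusted over the list alone. They were called lower at 0.0111, against an adjusted p = 0.601 with an estimated correlation. Markers of B cells were called lower at 0.0361, against an adjusted p = 0.261 with an estimated correlation: Cd79b (-0.82) and Vpreb1 (-0.50) fell and 7 of 9 did not pass, with the same counts adjusted over the list alone. Markers of thymic stroma were called lower at 0.0388, against an adjusted p = 0.339 with an estimated correlation. Among them the epithelial genes Epcam (-1.06), Foxn1 (-0.36) and Ly75 (-0.33) fell, the endothelial gene Pecam1 (0.64) rose and 12 of 16 did not pass, with 1 higher and 4 lower adjusted over the list alone.

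Lists not called in this comparison were T-lineage transcription factors (0.151), V(D)J recombination (0.818), Notch targets (0.786), Wnt and beta-catenin targets (0.47), DP and later T cell maturation (0.347), NK and innate lymphoid markers (0.818), gamma-delta T cell markers (0.328), myeloid and dendritic cell markers (0.818), G2 and mitosis (0.833), Bcl-2 family (0.393), T-ALL oncogenes (0.347) and nucleolar and Myc-driven biosynthesis (0.787). Within them Ly6d (-2.39), Nkg7 (-1.18), Ccnd2 (-0.99) and Bcl2 (-0.92) fell, while Cd53 (1.84), Ccr9 (1.79), Ikzf3 (1.42), Icos (1.23) and Il2rb (0.86) rose. Notch1, Myc, Hes1, Dtx1, Il2ra, Bcl11b, Rag2, Cd4, Cd8a and Cdkn2a were not called.

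Of the 990 genes 927 did not overlap between the groups; 2030 (13.6%) of all genes did not, where chance gives 2.4%. The count was 457 and 431 without TCF-1-deficient replicates 1 and 3, 1702 with the batch as a term and 325 in the larger batch alone, and without TCF-1-deficient replicates 1 and 2 the lists called were 6 and 4 in place of 10. The lists that lost their call without at least 1 array were pre-TCR and CD3 signalling, T-ALL tumour suppressors, glycolysis, immediate-early and stress genes, S phase, B cell markers and thymic stroma markers, with adjusted p up to 0.106; in the larger batch alone immediate-early genes stood at 0.362. With the filter at the 50th percentile the calls of pre-TCR and CD3 signalling (0.149), T-ALL tumour suppressors (0.149), glycolysis (0.117), immediate-early genes (0.0752) and thymic stroma (0.425) ended. With a sex term 8 lists were called in place of 10, with thymic stroma and immediate-early genes both at 0.0507, and Lef1 was not called (0.0534). The call of thymic stroma also ended without a filter (0.0543) and with averaged rows (0.0707), as that of T-ALL tumour suppressors did with averaged rows (0.0728) and that of B cell markers with 1 fit to all 12 arrays (0.0632) and in the larger batch (0.069). In the larger batch alone Gata3, Ikzf1, Ddx58 and Zfp36 were not called. With quantile normalisation the calls of pre-TCR and CD3 signalling (0.177), T-ALL tumour suppressors (0.192), B cell markers (0.0585) and thymic stroma markers (0.152) ended. Of the 69 named and called genes 37 stayed called whichever array was left out; those that did not were Lef1, Id2, Ptcra, Rag1, Etv5, Slc44a1, Drd5, Cd28, Rasgrp1, Cd3e, Fyn, Sp5, Ccnd2, Fzd7, Ccr9, Nkg7, Il2rb, Icos, Vpreb1, H2-Ab1, Pecam1, Foxn1, Ly75, E2f2, Zmat3, Trp53inp1, Polk, Bcl2, Dnmt3a, Phf6, Pkm and Ifit1, with adjusted p up to 0.176 (Ptcra without TCF-1-deficient replicate 1). In the larger batch alone Ptcra changed by -0.35, Cd28 by 0.66, Trp53inp1 by 0.36 and Phf6 by 0.27, none of them called, and without TCF-1-deficient replicate 3 Fyn changed by 0.43.

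Genes that changed in TCF-1-deficient DN3 cells mostly lay on the same side of wild type in the lymphomas. Of the 85 genes that rose without TCF-1, 75 were higher in the lymphomas and 50 were called higher there. Of the 213 that fell, 179 were lower and 86 were called lower, and 5 genes were called in opposite directions. Against TCF-1-deficient DN3 cells 78 of the 298 genes were called back towards wild type in the lymphomas, 62 of them from below and 16 from above, and 28 were called further away. Of the latter, 27 named genes had calls in all 3 comparisons, including Ikzf3, Gimap4, Afdn, Pdgfrb, Itga4 and Atp8b4, and also Lef1, Fyn and Ccnd2, whose call against TCF-1-deficient DN3 cells ended without some single arrays. Tubb3 rose by 1.47 in TCF-1-deficient DN3 cells and was 1.22 below wild type in the lymphomas (a change of -1.22).

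Both comparisons used the same 3 wild-type arrays. Independent lists of these sizes share 2.52 rises and 6.10 falls. In 100 simulations that kept the called changes of the TCF-1-deficient cells and moved those of the lymphomas to random genes, shared arrays and chance put 59.6% of the rises and 59.6% of the falls on the same side (at most 75% and 70.9%), against the observed 88.2% and 84%. At most 6 rises and 10 falls were called in both, against 50 and 86. The TCF-1-deficient arrays are shared as well. Those simulations called 191 genes back towards wild type on average and at most 5 further away, against 78 and 28. They left most genes changed without TCF-1 at wild-type level in the simulated lymphomas. Many calls back and few further away were thus built in, and these counts do not measure what shared arrays alone give. Across genes, which are not independent replicates, the changes correlated at r = 0.433, below the 0.558 that 100 simulations of unchanged groups gave from shared controls alone. Their covariance was 0.0346 against a simulated 0.00992, a difference of 0.0246. With 3 wild-type arrays the controls could not be split, and batches and pairing were not simulated, so part of the excess in shared calls may come from the shared arrays. With the batch as a term 251 genes were called the same way in both comparisons in place of 136.

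**Figure D3:**
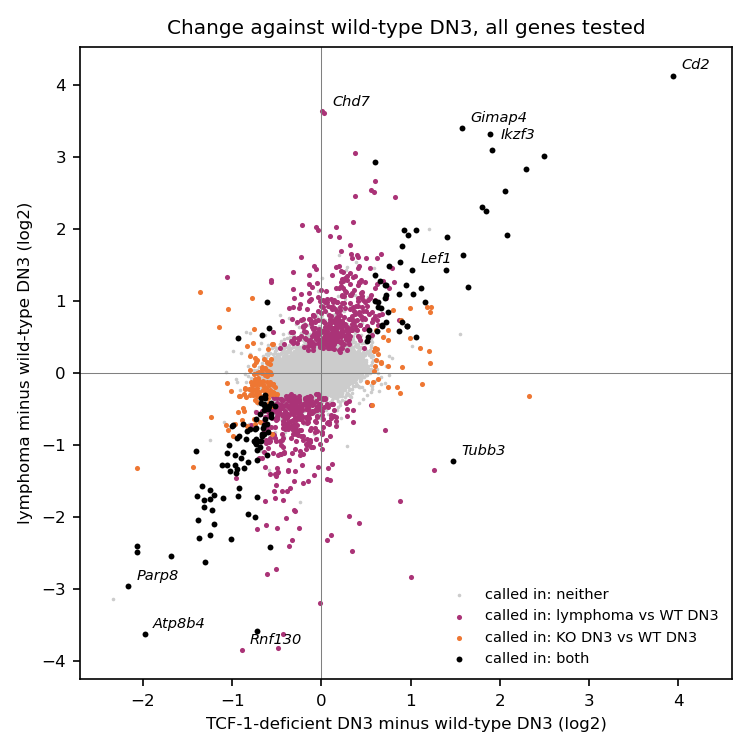
Log2 change against wild-type DN3 cells of each of the 14953 genes tested, in TCF-1-deficient DN3 cells (horizontal axis) and in lymphomas (vertical axis), which share the 3 wild-type arrays. Black points passed the test in both comparisons, 50 of them higher in both and 86 lower in both; orange and purple points passed in the comparison named in the key alone, and grey points in neither.

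The lymphomas were compared with each other for relations of Lef1 to genes of the Notch and E protein pathways, over 6 tumours and 5 relations. Lef1 and Id2 correlated at r = -0.75 (exact permutation p = 0.0875, adjusted 0.3) and rho = -0.89 (exact permutation p = 0.0333, adjusted 0.166). Leaving out lymphomas 1 and 3, the farthest from the median of Lef1, gave r = -0.58, and the 4 tumours of the larger batch gave -0.63. With Myc, r was -0.59 (exact permutation p = 0.233) and rho -0.43 (p = 0.419 by permutation), and r was -0.62 without lymphomas 1 and 3. With the mean of the G2 and mitosis list, r was -0.63 (exact permutation p = 0.178) and rho -0.54 (p = 0.297 by permutation); r was -0.16 without lymphomas 1 and 3. With the mean of the progenitor list, r was 0.52 (exact permutation p = 0.3) and rho 0.66 (p = 0.175 by permutation), and r was 0.52 without these tumours. With the mean of the Notch targets, r was 0.57 (exact permutation p = 0.249) and rho 0.71 (p = 0.136 by permutation), and it turned to -0.08 without lymphomas 1 and 3. With the arrays quantile-normalised again r was 0.21 for progenitor genes, -0.24 for G2 and mitosis, -0.42 for Myc, -0.67 for Id2 and 0.82 for Notch targets. No relation passed after Benjamini-Hochberg adjustment, at 0.3 for every r and 0.166 or more for every rho. Within the larger batch r was -0.59 for Myc, -0.92 for G2 and mitosis, 0.89 for progenitor genes and 0.10 for Notch targets, over 4 tumours, and the smaller batch held too few lymphomas for a value.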

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

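Every test in this part was chosen after the result it bears on was seen, apart from the distance check on the 6 lymphomas, which follows a fixed rule.

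Among the 209 genes named by the rule, 13 had 1 lymphoma farther from the others than Dixon's 95% limit, or 6.2%, where chance marks about 1 group in 20. The number is therefore close to what chance gives. Lymphoma 1 stood apart with Gria3 at 4.35, against 7.13 to 7.52 in the other tumours, with Akr1c13 at 6.64 against 4.44 to 5.02, and with the keratin gene Krt18 at 5.71 against 4.58 to 4.98. Lymphoma 3 had Il7r at 8.26, against 5.67 to 6.54 elsewhere, and Atp8b4 at 6.35, against 4.93 to 5.21. Lymphoma 4 had Ctla4 at 6.72, against 5.80 to 6.09, and Ctnnd1 at 7.28, against 7.81 to 8.07. Lymphoma 2 had Il2ra at 9.89, against 10.35 to 10.62, Polr1b at 5.85, against 6.11 to 6.27, and Cdkn2a at 5.02, against 5.33 to 5.48. Lymphoma 6 had Xrcc6 at 9.32, against 8.91 to 9.03, and Epcam at 4.59, against 4.84 to 4.96. Lymphoma 5 had Ifitm3 at 5.12, against 5.76 to 6.08.

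The 12146 rows without a gene name here, which the comparisons of genes do not use, also carried differences. Tested alone with limma, 120 were called between lymphomas and wild-type DN3 cells, 66 higher and 54 lower, with changes from -4.54 to 5.01. Between lymphomas and TCF-1-deficient DN3 cells 110 were called, 90 higher and 20 lower. None was called between the DN3 groups, where 918 had an unadjusted p under 0.05. What these rows measure was not analysed here.

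For the count of genes called between TCF-1-deficient and wild-type DN3 cells, 1 of the 10 splits of the 6 arrays, the real one, gave 298 genes and the highest other gave 0, but 10 splits are too few for a share under 0.05. For lymphomas, 1 of 84 splits gave as many as the real 871 genes against wild-type DN3 cells. Against TCF-1-deficient DN3 cells 1 of 84 gave as many as the real 990. Both shares are under 0.05. Other splits with calls numbered 8 and 4, and the highest of them, 545 and 339, followed the smaller batch. The batch thus makes the splits unequal, so these shares are not p-values and do not by themselves exclude chance. Batch alone is argued against by the design, since each group has the same share of both batches; 100% of the called genes also kept their sign within both batches in each of the 3 comparisons, which adds little because the arrays of nearly all called genes do not overlap between groups. Sex as the whole source is argued against by the design, since TCF-1-deficient replicates 1 and 2 and lymphomas 3, 4 and 5 have high Xist like every wild-type array; with a sex term the lower quartile of the ratio of log2 changes was 0.911, 0.913 and 0.968, which adds little for the same reason as the signs. The sex term still lowered the first count from 298 to 126, because only TCF-1-deficient replicate 3 differs from the other DN3 arrays in Xist and the term removes it from the contrast, leaving fewer arrays; age of the lymphoma-bearing mice stays open and untested.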

How the results depend on the processing

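The batch term, the larger batch alone, the sex term and SDs within batches were chosen after the data were seen; the other alternatives were fixed before. Of the counts and summaries 122 kept to within 1.5 times or the spread, 26 moved and 1 reversed, and the cause was not tested except where fewer arrays or a blocked spread is the alternative's own construction. Genes called for TCF-1-deficient against wild-type DN3 cells (298) ranged from 57 (without wild-type replicate 2) to 443 (without TCF-1-deficient replicate 2) when single arrays were left out. They came to 1380 with the replicate block, 754 with the batch as a term, 144 in the larger batch alone and 126 with the sex term. Lymphomas against wild-type DN3 cells (871) gave 560 to 872 with an array left out and 549 in the larger batch alone. Lymphomas against TCF-1-deficient DN3 cells (990) gave 431 to 1361, 1702 with the batch as a term and 325 in the larger batch alone. The replicate block gave 863 and 999 in these 2 comparisons, where the numbers do not pair the arrays. It used only lymphomas 1, 2 and 3, whose numbers the DN3 arrays share. Of the 871 and 990 calls it kept 646 and 639. Lists called (6, 10 and 10) fell to 0 in each comparison with an estimated correlation, and ranged from 3 to 9, 6 to 12 and 4 to 10 with an array left out. In the third comparison they were 6 with quantile normalisation and 5 with the filter at the 50th percentile. The 136 shared calls became 251 with the batch as a term. The relation of Lef1 to Notch targets turned from 0.57 to -0.08 without lymphomas 1 and 3. Other settings left counts within 1.5 times: median-centring gave 322, 832 and 1039, quantile normalisation 234, 917 and 939, and no filter 256, 856 and 946. Of the named genes' values 89, 118 and 168 lost their call under some setting, 55, 32 and 38 gained one, and no called value reversed, which adds little as the arrays of nearly all called genes do not overlap between groups. Between the DN3 groups no named gene or list that was called lost its call with the replicate block. Of the lists' values 12, 25 and 50 lost their call and 19, 10 and 0 gained one. The level of the deleted gene was not run. Signal near the floor limits dim genes. The filter left out those with a mean under log2 4.78 only. Genes little above that level stayed in, such as Sp5 at 4.85 in wild-type and 5.52 in TCF-1-deficient DN3 cells.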

Other observations

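The tests of chromosomes, of the neighbourhood of the deleted gene and of single tumours in this part were chosen after the results were seen.

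Some genes stood far higher or lower in single tumours than in the other tumours. The genes of this paragraph were taken from those with the largest SD among the lymphomas, after their values were seen. Kcnma1, a potassium channel gene, reached 10.66 in lymphoma 4 and 7.10 in lymphoma 2, against 4.09 to 4.37 in the other 4. Plod2, a collagen-modifying enzyme gene, stood at 7.88 in lymphoma 6 and at 3.92 to 4.10 in the rest. Ly86 and Ly6k stood at 8.19 and 9.01 in lymphoma 1, the iron exporter gene Slc40a1 at 7.43 in lymphoma 3 and the germ cell gene Tex14 at 7.56 in lymphoma 2. The mast cell protease gene Cpa3 ranged from 5.62 to 9.40 over the tumours and the stem cell antigen gene Cd93 from 5.52 to 8.38. Trgv1, a variable segment of the T cell receptor gamma locus, was at 9.95 to 11.14 in 5 tumours and at 7.37 in lymphoma 6. The Y-linked gene Eif2s3y stood at 3.63 in lymphoma 6, as on arrays with high Xist, and at 6.81 to 7.96 on the other 3 arrays with low Xist, although Uty and Kdm5d were high on all 4. Of all genes tested 32 had an SD over 1 among the 6 lymphomas, against 4 among the wild-type and 11 among the TCF-1-deficient DN3 arrays. Among the 32 were Xist, Uty and Kdm5d, which follow sex. Macrod2 followed the batch, at 5.22 and 5.17 in lymphomas 1 and 2 and at 7.47 to 7.99 in the others. The groups also differ in their number of arrays, so these counts do not settle which group varied most.

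A set of 27 genes moved in TCF-1-deficient DN3 cells and moved further in the same direction in the tumours, with calls in all 3 comparisons. Besides those already named it included rises of the calcium-dependent kinase gene Camk4 (1.05, then 1.99 against wild type), the phosphatase gene Dusp10 (0.92, then 1.99) and the chemokine receptor gene Ccr4 (0.76, then 1.49). Falls included Tcf7l2, another gene of the same transcription factor family (-0.61, then -1.13), the chromatin remodeller gene Smarca4 (-0.72, then -1.20) and the diacylglycerol kinase gene Dgke (-1.20, then -2.09). Among genes called in all 3 comparisons, another 6 named ones turned back or reversed in the tumours: Camsap2, Emb, Fabp5, Prkar2a, Tmem176b and Tubb3. The genes of this paragraph were likewise named after their values were seen.

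Genes of chromosome 14 were shifted upwards in all 6 lymphomas, by most in lymphomas 3 and 5 and by 0.036 to 0.074 (adjusted p = 0.000218 to 0.002 by permutation) in the other 4, where it was not particular, as other chromosomes moved as far or further: X by 0.12 and 13 by 0.094 in lymphoma 1, 12 by 0.092 in lymphoma 2, 18 by -0.074 in lymphoma 4 and 13 by 0.09 in lymphoma 6. For this, 373 genes of chromosome 14 in the brighter part of all genes were set against DN3 arrays of the same batch. Their median lay 0.213 above that of the other chromosomes in lymphoma 5 and 0.179 in lymphoma 3. The permutation p = 1e-05 is the smallest that 100000 draws can give (adjusted 0.000171 over 120 tests), and it treats genes as independent. Wild-type DN3 replicate 2 reached the same permutation p on chromosome 13, with a shift of 0.073 while itself part of the reference. The p therefore does not set tumours apart from DN3 cells. Other chromosomes of lymphomas 3 and 5 moved by at most 0.037. Single DN3 arrays, set against the other DN3 arrays of their batch, moved by at most 0.102 (chromosome 13). On chromosome 14 they moved by at most 0.021. An array-wide offset cancels in these shifts, which are taken against the other chromosomes of the same array, so that 0.037 does not test it. A few strongly changed genes are argued against by the 71.8% or more of chromosome 14 genes above the median of the other chromosomes. An extra copy of the chromosome in the tumour cells is a candidate explanation. All 5 parts of the chromosome moved up in these 2 tumours, by at least 0.084. That is within the 0.102 of chromosome 13 in a DN3 array and above the 0.021 of the whole chromosome 14. However, genes of the dim part moved by only 0.049 and 0.063, below that 0.102, and those of the bright part by 0.283 and 0.343. These values are below the 0.585 that 3 copies in place of 2 would give in every cell. DNA was not measured, and array signals compress small changes. The smaller shift of the other 4 tumours is within that of DN3 arrays over all chromosomes, but above their 0.021 on chromosome 14. Of the chromosome 14 genes 6.1% were called higher in lymphomas against wild type, where other genes gave 2.8%.

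Mice made from stem cells of another strain can keep donor DNA around the deleted gene, which could give differences at its neighbours. Among the 200 tested genes nearest to the deleted gene 3 were called between the DN3 groups, an odds ratio of 0.746 (95% interval 0.152 to 2.23, Fisher's exact test p = 0.801). They included Thg1l and Adam19, which is among the largest rises without TCF-1 given above. Between lymphomas and wild-type DN3 cells 14 were called, with an odds ratio of 1.22 (95% interval 0.652 to 2.11, p = 0.446 by Fisher's exact test), among them Rnf130 and Adam19. Both intervals hold 1 and reach past 2, so an excess near the deleted gene cannot be told apart from none. Genes are not independent replicates in this test.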
